A study of Silurus lanzhouensis with 6 samples.

How the data were processed

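Back muscle was taken from 6 fish of Silurus lanzhouensis, 3 labelled heaviest and 3 labelled lightest, and total RNA was sequenced after library preparation with standard Illumina protocols, per the labels' protocols. Groups and replicate numbers were taken from the labels. Both groups came from the same tank, and no batch, lane or sequencing date is given in the labels.

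The expression values are FPKM, fragment counts scaled by transcript length and library size, deposited by the authors with 1 column per fish and 1 value per cluster ID, rounded to 2 decimals. The read trimming, assembler, clustering, aligner, counting and any comparison the authors ran between groups are not given in the sources used here. A deposited table of other summary values lists, per the file headers, how many clusters of each fish fall into 6 FPKM intervals, and a recount from the FPKM values differed in 0 of its 36 cells. Other deposited tables give, per the file headers, the length in bases of each assembled transcript and a summary of the assembly, and the lengths recomputed here gave the same N50 of 1496 and N90 of 287. The transcript IDs, with or without their last part, shared 0 IDs with the FPKM table. The part of a cluster ID before the point is called its first number here. There were 24126 first numbers, and 60758 of the 89579 clusters (67.8%) had the first number 6468, which held 98.6% of summed FPKM. The next most frequent first number had 16 clusters.

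FPKM values are divided by transcript length and by library size, so library depth cannot be read from their sums, which ran from 930285 to 1024978. Where whole fragments are counted, the low values of a cluster are whole multiples of the value of 1 fragment. Such steps were searched in 38900 clusters with values up to 1.5 FPKM in at least 3 fish. A common step was found in 9614 of them (24.7%), against 4.2% after random changes to the values. The median step was 0.17 FPKM and the 95th percentile 0.354 FPKM, which is the size of 1 fragment in those clusters. The ratios of steps between fish gave relative depths, and different pairs of fish gave values within 0.011 on the log2 scale of each other. On simulated reads for 60000 clusters the largest error of a relative depth was 0.05%. Those reads were whole fragments with 1 step per cluster, so this error covers the calculation and not its accuracy in these data. With a median step of 0.17 FPKM, clusters near that level rest on a few fragments. A cluster with a value over 1.5 FPKM in any fish could not enter the search. The value of 1 fragment can be larger in such clusters, so higher levels may also rest on a few fragments. Recovered fragments were not used in a count test, because most clusters gave no common step.

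The design, tests, rule for named clusters and most of the other settings were fixed before the data were examined. The comparison used limma 3.58.1 in R 4.3.3, with a linear model of 2 groups, a variance trend with abundance, a two-sided test and Benjamini-Hochberg adjustment. Values entered as log2(FPKM + 1), so fold changes are on that scale and understate changes of low clusters. Clusters with a mean of at least 1 FPKM over the 6 fish were tested, 28592 in all (31.9%), and an adjusted p under 0.05 was the threshold, with no minimum fold change. The design had been written for transcripts or genes, and the deposited table holds clusters, so clusters were tested. Values per fish were compared with exact permutation tests, and calls in classes of abundance with Fisher's exact test. Descriptive steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

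The rule for named clusters took, where IDs are not paired with names, the 2 IDs higher and the 2 IDs lower in the heaviest fish with the smallest p among those whose groups do not overlap. The most abundant cluster and the most abundant cluster called lower were added after their values were seen.

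The limma step was tested on simulated data for the comparison of heaviest and lightest fish, with 28592 clusters of which 200 were changed. It recovered 3 of 67 clusters changed by 1 on the log2 scale, 31 of 67 changed by 2 and 57 of 66 changed by 4. It made 11 false calls, and 0 calls when no cluster was changed. As a share of all its calls, the 11 were above the threshold of 0.05. Changes were placed only in clusters with a mean log2(FPKM + 1) of at least 2. Clusters at 0 throughout 1 group, 321 of the 350 calls in the real data, were not simulated as such. Other splits of the real fish gave 10 to 22 calls, so the 0 calls describe the simulated data only. With 3 fish per group, changes of 1 on the log2 scale were mostly not detectable in the simulation.

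Alternatives were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 FPKM, median-ratio, upper-quartile and quantile scaling, limma without a trend, with a robust trend and with sample weights, a minimum of 2-fold, the replicate number as a block, other detection limits and each fish left out in turn. Tests without clusters at 0, the adjustment of p-values over the kept clusters alone, each fish left out for the similarity of fish and for clusters found only in 1 group, and the settings for the pair of abundant clusters were added after the data were seen.

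Gene lists for muscle growth and for other cell types had been fixed beforehand and were not tested, because the files used here pair no cluster ID with a gene name. Classes of transcript length and the relation of fold change to length were not run, because no lengths could be joined to clusters. No genome was used, so no position or sequence is given.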

Results

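RNA sequencing of back muscle was used to compare the 3 heaviest and the 3 lightest fish taken from a shared rearing tank of the catfish Silurus lanzhouensis. The fish descended from selected female stock crossed with wild male stock and had been kept for 16 weeks in flowing pond water at about 24 °C. The comparison asks which muscle transcripts differ between fish at opposite ends of the range of body weight. Each library came from a separate fish, so the spread within a group is the spread between fish. Expression was given in FPKM, in which fragment counts are scaled by transcript length and library size, for 89579 clusters, the units of the deposited expression table. Of these, 37809 clusters were above 0 in all 6 fish and 5717 were listed at 0 in all 6. Absolute depth is unknown, because no read counts were used here. The steps between low FPKM values gave each library's depth relative to the geometric mean of the 6. Relative depth was 1.016, 0.918 and 1.072 in heaviest fish 1, 2 and 3. It was 1.076, 1.02 and 0.911 in lightest fish 1, 2 and 3. Mean relative depth was 1.002 in both groups (exact permutation p = 1.0, two-sided, n = 3 fish per group).

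**Figure D1:**
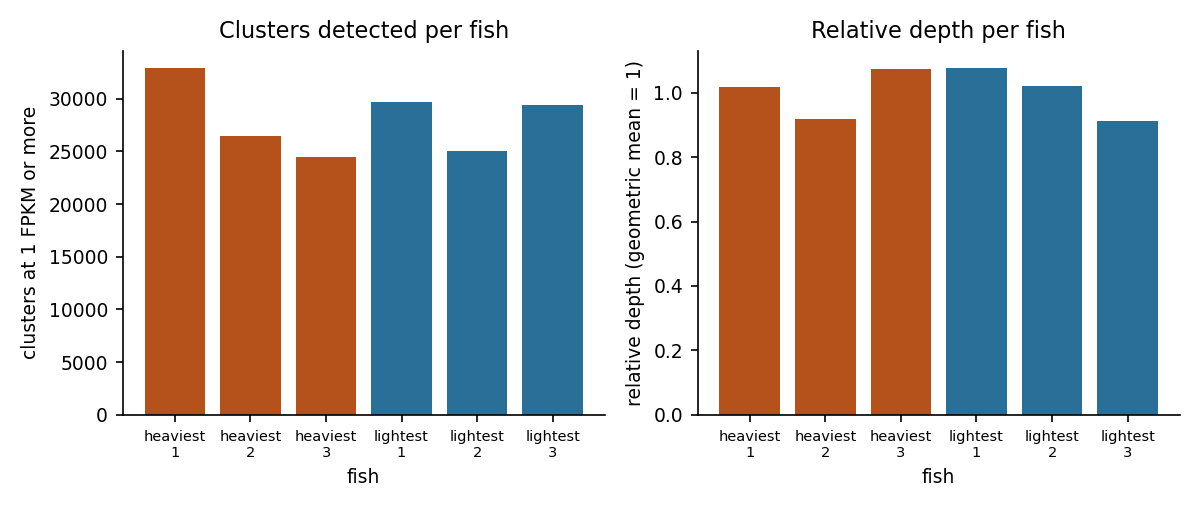
Bars show, for each of the 6 fish, the number of clusters at 1 FPKM or more (left) and the depth of the library relative to the geometric mean of all 6 (right), with heaviest fish in orange and lightest fish in blue. Detected clusters ran from 24471 to 32888 and relative depth from 0.911 to 1.076, and both groups covered overlapping ranges.

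The libraries of the heaviest and the lightest fish differed most plainly in clusters found in every fish of 1 group and listed at 0 in every fish of the other. At 1 FPKM or more, 358 clusters were found in all 3 heaviest fish and listed at 0 in all 3 lightest fish. In the opposite direction, 447 clusters were found in all 3 lightest fish and listed at 0 in all 3 heaviest fish. The other 18 sets of 3 fish had between 30 and 83 such clusters each, with a median of 48.5. The clusters found only in the heaviest fish had a median level of 2.54 FPKM and reached 122.5 FPKM, and 11 of them were at 20 FPKM or more. Those found only in the lightest fish had a median level of 2.45 FPKM and reached 145.8 FPKM, and 29 of them were at 20 FPKM or more. With a minimum of 5 FPKM the numbers were 54 and 82, against 3 to 13 in the other sets of 3. With a minimum of 0.5 FPKM they were 748 and 986, against 68 to 196. The numbers depend on how many fish must meet the criterion: 608 clusters were found only in the heaviest fish without heaviest fish 2, 580 without heaviest fish 3, and 721 were found only in the lightest fish without lightest fish 2. A value of 0 in the deposited table is a listed 0 and does not show that a transcript was absent. Whether the group labels entered the making of the clusters is not given in the sources used here. Of the clusters found only in the lightest fish, 216 had a first number under 2000. Other clusters in that range were above 0 in 6.2% of cases in the heaviest and 85.1% in the lightest fish, on average. Whether the clusters found only in 1 group reflect expression in muscle is not known.

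**Figure D2:**
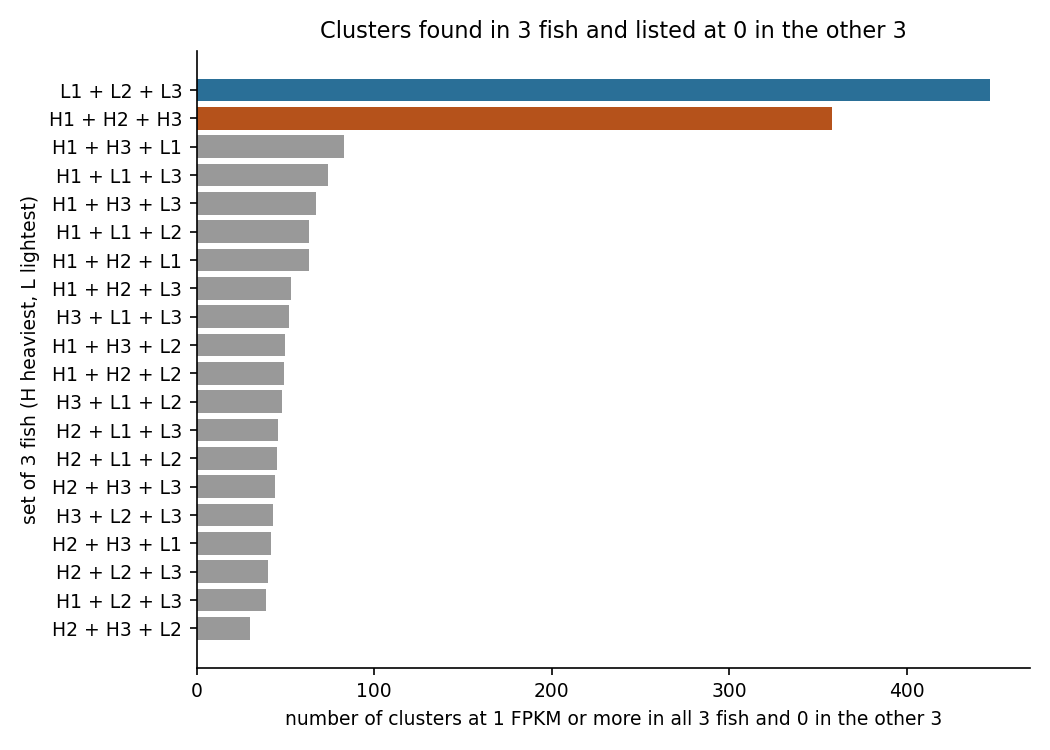
Bars give the number of clusters at 1 FPKM or more in all 3 fish of a set and listed at 0 in the other 3, for each of the 20 sets of 3 fish (H heaviest, L lightest). The sets made of the 3 lightest (447) and the 3 heaviest fish (358) lie above the other 18 sets, which reach 83 at most.

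The files pair no cluster ID with a gene name, so single clusters are given by ID. The 2 clusters higher in the heaviest fish with the smallest p were both listed at 0 in every lightest fish. Cluster-6468.32041 was at 125.31, 116.5 and 125.56 FPKM in heaviest fish 1, 2 and 3 (limma adjusted p = 4.89e-05). Cluster-16941.0 was at 54.16, 71.99 and 56.97 FPKM in the same fish (limma adjusted p = 6.47e-05). The 2 clusters lower in the heaviest fish with the smallest p were both listed at 0 in every heaviest fish. Cluster-6468.54202 was at 139.77, 131.95 and 165.73 FPKM in lightest fish 1, 2 and 3 (limma adjusted p = 4.89e-05). Cluster-6468.6744 was at 106.42, 103.36 and 122.99 FPKM in the same fish (limma adjusted p = 4.89e-05). No fold change is given for these clusters because the other group was listed at 0. That group had no spread between fish, so these p-values can be too small.

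**Figure D3:**
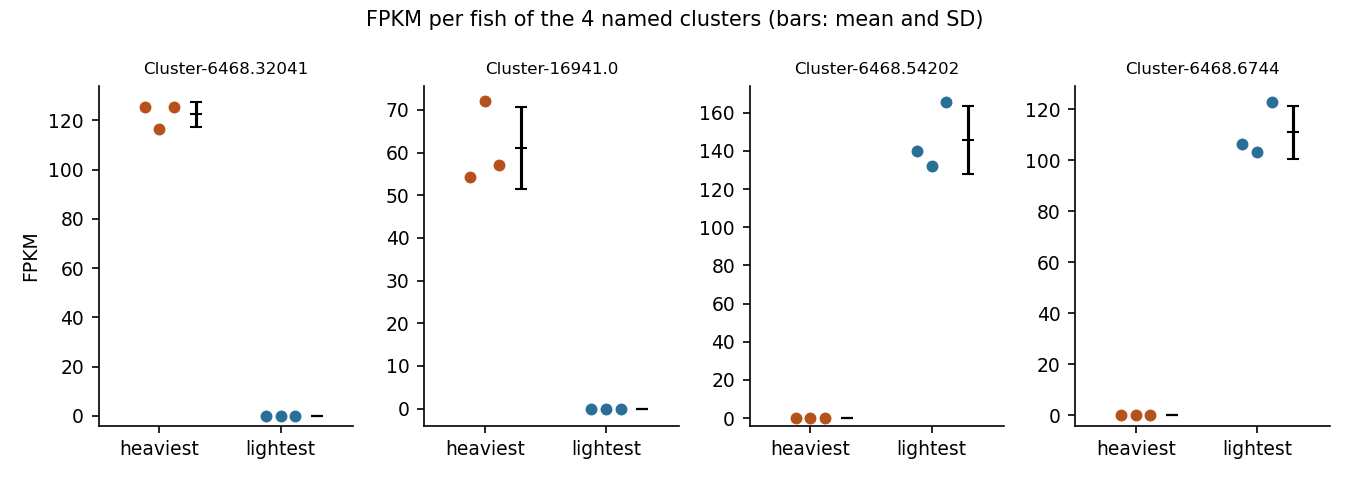
Points give the FPKM of each fish for the 4 named clusters, with the mean and SD of each group of 3 beside them. Cluster-6468.32041 and Cluster-16941.0 are at 0 in the lightest fish, and Cluster-6468.54202 and Cluster-6468.6744 are at 0 in the heaviest fish.

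Across the 28592 clusters with a mean of at least 1 FPKM, limma called 350 different between the groups at an adjusted p under 0.05. Of these, 164 were higher and 186 lower in the heaviest fish. Clusters listed at 0 throughout 1 group made up 321 of the 350 calls, 146 of them higher and 175 lower in the heaviest fish. Such clusters numbered 1980 among those tested, so 16.21% of them were called. Being at 0 throughout 1 group is itself a difference between the groups, so the 321 describe the calls and are no test of them. The group at 0 shows no spread between fish but counts in the limma estimate of the spread. The p-values of such clusters can therefore be too small. The other 29 calls, 18 higher and 11 lower in the heaviest fish, were above 0 in at least 1 fish of both groups. Within those 29, the 14 clusters above 0 in all 6 fish divided into 7 higher and 7 lower. The median log2 fold change over all tested clusters was -0.03, on the log2(FPKM + 1) scale. That is smaller than the SD of 0.134 between fish of their median log2 level. FPKM is already scaled by library size, so this describes the scaled values and cannot show whether total expression differed. Tested without clusters at 0 in all 3 fish of a group, 10 of the 29 were called, 8 higher and 2 lower in the heaviest fish. Among the 22745 clusters above 0 in all 6 fish limma called 0 of the 14, with 1748 at an unadjusted p under 0.05. Adjusting the p-values of the full limma test over the kept clusters alone also gave 10 and 0. A narrower adjustment thus ends these calls without any change in fold. With a mean of at least 5 FPKM 62 were called. The replicate number as a block gave 163 calls, 71 higher and 92 lower, though the labels do not say that it pairs fish. Leaving out any heaviest fish raised the calls higher in the heaviest fish, to 240, 276 and 273 without heaviest fish 1, 2 and 3. Leaving out any lightest fish raised the calls lower in the heaviest fish, to 280, 357 and 274 without lightest fish 1, 2 and 3. The shift thus followed the group of the fish left out and was not particular to 1 fish.

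**Figure D4:**
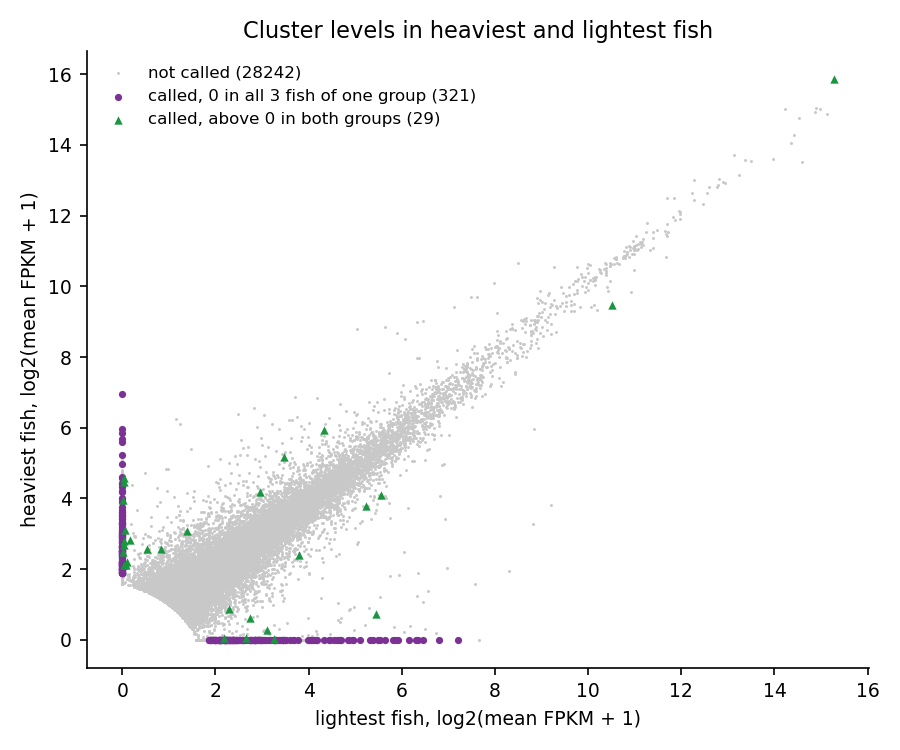
Each point is 1 of the 28592 tested clusters, placed by log2(mean FPKM + 1) in the lightest fish (horizontal) and in the heaviest fish (vertical). Purple points, the 321 called clusters at 0 in all 3 fish of a group, lie along the axes, and green triangles mark the 29 other called clusters.

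A pair of abundant clusters, singled out after their values were seen, also passed the threshold in the main limma test. The most abundant cluster of the table was at 59971 ± 5589 FPKM in the heaviest and 39623 ± 3623 FPKM in the lightest fish (SD, n = 3 each). Its log2 fold change was 0.60 with an SE of 0.09, or 1.51-fold, and all 3 heaviest fish were above all 3 lightest (limma adjusted p = 0.0387). The most abundant of the clusters called lower, at rank 128, was at 712 ± 75 FPKM in the heaviest and 1456 ± 256 FPKM in the lightest fish (SD, n = 3 each). Its log2 fold change was -1.02 with an SE of 0.15, and all 3 heaviest fish were below all 3 lightest (limma adjusted p = 0.0376). Across 19 other settings of the limma test the log2 fold change ran from 0.13 (quantile normalization) to 0.68 for the most abundant cluster and from -1.15 to -0.88 for the cluster at rank 128. Both calls were marginal: the most abundant cluster was under 0.05 in 2 of these 19 settings, with limma adjusted p from 0.0167 to 0.765, and the cluster at rank 128 in 4 of 19, with adjusted p from 0.0244 to 0.428. Neither passed when any single fish was left out, with limma adjusted p of 0.189 to 0.631 for the most abundant cluster and 0.0828 to 0.190 for the other. Both were above 0 in all 6 fish, and tested among such clusters alone each had a limma adjusted p of 0.428. Their calls thus rest on an adjustment that includes the clusters at 0 in 1 group.

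By abundance, 303 of the 23610 clusters with a mean of 1 to 10 FPKM were called, 147 higher and 156 lower in the heaviest fish. That was 1.28%, against 0.943% of the remaining clusters (Fisher's exact adjusted p = 0.0942, over 4 classes). Between 10 and 100 FPKM, 45 of 4370 clusters were called, 16 higher and 29 lower. That was 1.03%, against 1.26% of the rest (Fisher's exact adjusted p = 0.309). Between 100 and 1000 FPKM, limma called 0 of 479 clusters, against 1.25% of the rest (Fisher's exact adjusted p = 0.0206). Of the 350 calls, 321 were clusters at 0 throughout 1 group. Clusters found in every fish of 1 group and at 0 in the other reached at most 145.8 FPKM where found. Averaged over all fish they lie under 100 FPKM, so such calls could not fall in this class. The test therefore cannot separate an effect of abundance from where the clusters at 0 in 1 group lie. At 1000 FPKM and over, 2 of 133 clusters were called, 1 in each direction (Fisher's exact adjusted p = 0.679). Clusters are not independent replicates, so these p-values describe the set of clusters and not the fish. The class of 1 to 10 FPKM passed the threshold with a pseudocount of 0.1 (adjusted p = 0.00129) and with upper-quartile scaling (adjusted p = 0.0156), and the class of 10 to 100 FPKM passed it with a pseudocount of 0.1 (adjusted p = 0.0110).

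The number of clusters detected did not separate the groups. At 1 FPKM or more, 27930 ± 4404 clusters were detected in the heaviest and 28015 ± 2577 in the lightest fish (SD, n = 3 each, exact permutation p = 1.0, two-sided). A comparison of 3 fish with 3 cannot give a p below 0.1. The direction of this difference of -84.7 clusters turned to 664.8 without heaviest fish 2, to 1644.8 without heaviest fish 3, to 722 without lightest fish 1 and to 594.5 without lightest fish 3. It kept its direction at -2563.7 without heaviest fish 1, at -1570.5 without lightest fish 2 and at -1551.3 with a limit of 0.1 FPKM. The 100 most abundant clusters of each fish held 62.3% ± 3.49 of summed FPKM in the heaviest and 60.7% ± 1.85 in the lightest fish (SD, n = 3 each, exact permutation p = 0.6, two-sided). That difference turned to -0.32 percentage points without heaviest fish 3. In the authors' intervals, clusters over 60 FPKM made up 1.04% ± 0.12 in the heaviest and 1.09% ± 0.06 in the lightest fish (SD, n = 3 each, exact permutation p = 0.8, two-sided).

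Fish of the same group had on average slightly higher correlations with each other than with fish of the other group, a difference that 3 fish against 3 cannot bring under p = 0.1. The mean Pearson correlation of log2(FPKM + 1) across tested clusters was 0.818 within groups and 0.786 between groups, a difference of 0.0316 (exact permutation p = 0.1, one-sided, n = 3 fish per group). Pairs of lightest fish were at 0.838 to 0.851 and pairs of heaviest fish at 0.768, 0.772 and 0.835. Pairs across groups ran from 0.721 to 0.832, so the higher values within groups lay mainly in the lightest fish. Heaviest fish 1 stood apart, with a mean correlation of 0.751 with the other 5 fish, against 0.805 to 0.818 for the others. On the principal component with the largest share of variance (31.3%) heaviest fish 1 lay at -139.62 and the other 5 fish between 1.38 and 57.32. Heaviest fish 1 also had 973 clusters at 1 FPKM or more that were listed at 0 in the other 5 fish, against 360 to 556 for each of the others. The difference of 0.0316 fell to 0.0175 without lightest fish 1 and to 0.0148 without lightest fish 3. It rose to 0.0531 without heaviest fish 2 and to 0.0497 without heaviest fish 3. The exact permutation p (one-sided) was 0.3, 0.2 and 0.4 without lightest fish 1, 2 and 3, where 0.1 could be reached. Without each heaviest fish it was 0.1.

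The authors' transcript assembly held 163949 transcripts with a total of 129251738 bases, and the authors' deposited summary gave an N50 of 1496 bases and an N90 of 287 bases. N50 is the length at which transcripts of that length or longer hold 50% of all assembled bases. The mean transcript length was 788 bases and the median 384, within a range of 201 to 24492. Transcripts under 500 bases made up 61.0% of the assembly, and those of 2000 bases and over made up 9.5%. Transcript lengths were not joined to expression, because the transcript IDs and the cluster IDs had 0 IDs in common.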

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

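The settings that handle clusters at 0, the leave-one-out values for similarity and for clusters found only in 1 group, and all settings for the pair of abundant clusters were chosen after the results were seen; the others were planned. The 350 calls of limma became 62 with a mean of at least 5 FPKM. They became 10 without clusters at 0 in all 3 fish of a group and 0 among clusters above 0 in all 6 fish. Clusters at 0 throughout 1 group, 321 of the calls, were left out of the latter pair by construction. Among the 22745 clusters above 0 in all 6 fish, 1748 were at an unadjusted limma p under 0.05. The kept clusters had held 29 and 14 calls, and the p-values of the full limma test adjusted over the kept clusters alone gave 10 and 0, so the adjustment without the left-out clusters accounts for this loss. Leaving out each fish gave 425 to 516 calls, more than with all 6 fish. Of these, 290 to 305 were shared with the 350. The remaining settings without a block gave 327 to 514, and the median log2 fold change stayed between -0.12 (without heaviest fish 1) and 0.05 (without heaviest fish 3). All 4 named clusters kept their direction and an adjusted p under 0.05 in 10 of 10 limma alternatives, up to 0.00559. They had been picked by smallest p and were at 0 in every fish of 1 group, so their direction could not turn.

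With a replicate block limma called 163 clusters (71 higher and 92 lower in the heaviest fish), 160 of them shared with the 350. The replicate numbers share no stated origin. Deviations of same-numbered fish correlated at 0.171, 0.065 and 0.056 and those of other pairs at -0.104 to 0.051. Only 0.171 stood apart, so these values cannot show that the numbers pair fish.

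Clusters found only in the heaviest or only in the lightest fish numbered 748 and 986 (1734 together) at 0.5 FPKM and 54 and 82 (136 together) at 5 FPKM, by construction of the limit. Leaving out each fish gave 405 to 608 (without heaviest fish 2) and 503 to 721 (without lightest fish 2). The share called at 1 to 10 FPKM was 1.68% with a pseudocount of 0.1 and 1.34% with upper-quartile scaling. Both were past the threshold and above the share of the rest. At 10 to 100 FPKM it was 1.098% with a pseudocount of 0.1, also past the threshold but below the 1.647% of the rest. The cause was not tested. Detected clusters per fish differed by -2563.7 (without heaviest fish 1) to 1644.8 (without heaviest fish 3) and also reversed at 664.8 (without heaviest fish 2), 722 (without lightest fish 1) and 594.5 (without lightest fish 3); the share of the 100 most abundant clusters differed by -0.32 (without heaviest fish 3) to 3.14 percentage points. The cause was not tested for either. The difference in similarity was 0.0148 to 0.0586 in all its settings. Depth limits clusters near 0.17 FPKM, the median value of 1 fragment among clusters with values up to 1.5 FPKM. In other clusters the value of 1 fragment is unknown, so higher levels may also rest on a few fragments.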

Other observations

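All tests of explanations given here were chosen after the results they bear on were seen.

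Among the 10 most abundant clusters, which were looked up after the results were seen, the largest fold changes were at ranks 6 and 10 and did not pass the test. The cluster at rank 6 was at 33442 ± 8080 FPKM in the heaviest and 19285 ± 2986 FPKM in the lightest fish (SD, n = 3 each, limma adjusted p = 0.300). The cluster at rank 10 was at 11783 ± 7847 FPKM in the heaviest and 24673 ± 1470 FPKM in the lightest fish (SD, n = 3 each, limma adjusted p = 0.472). In the cluster at rank 10 the 3 heaviest fish were at 6129, 8477 and 20742 FPKM. Without gene names it stays open which muscle transcripts these are.

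The real grouping gave 350 calls, and the highest of the other splits of the 6 fish gave 22, so 1 of 10 splits gave as many. With 10 splits the share cannot fall under 0.05.

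For the clusters found only in the heaviest or only in the lightest fish, lower depth in the group at 0 is argued against by equal depth (a difference of -0.05%) and by 54 such clusters in the smaller direction at 5 FPKM, against 13 in the highest other set of 3 fish. Splitting of the large family of clusters with the first number 6468 as the whole cause is argued against by 194 such clusters outside it in the smaller direction, against 28 in the highest other set. A shared RNA source for each group, such as reads of another organism, may hold the levels of its clusters together. In the heaviest fish the median SD of log2 FPKM between fish was 0.282 against 0.388 in level-matched clusters, with 0 of 10000 draws as low. Without heaviest fish 1, which stood apart from the others, it was 0.242 against 0.297, with 8 of 10000 draws as low. In the lightest fish it was 0.276 against 0.289, with 1267 of 10000 draws as low. With 1 of these fish left out, 26 to 211 draws were as low, so the lightest fish gave no single answer. Clusters are not independent, so the draws do not measure the spread between fish. Steady levels could equally go with the causes named next, so the test cannot single out a shared RNA source. A library batch that follows the groups, a clustering of transcripts that used the group labels, sequence variants shared within a group through family, and a difference tied to body weight were not tested and stay open.

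Heaviest fish 1, with 973 clusters of its own, is the fish that most departs from the others. Greater depth as the cause is argued against by its relative depth of 1.016, since heaviest fish 3 and lightest fish 1 were deeper and had at most 556 clusters of their own. A smaller share taken by the most abundant clusters is argued against by lightest fish 3, which had a lower share (58.89% against 59.06%) and 469 clusters of its own. Other cell types in the piece of muscle and a trait of that fish were not tested and stay open.

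Leaving out the first number 6468, clusters found only in the lightest fish also lie together in the cluster numbering, with 216 of the 2206 clusters whose first number is under 2000 against 12 of the 24310 with first numbers of 4000 and over. Among clusters outside the set, 6.2% of those numbered under 2000 were above 0 in the heaviest fish on average, against 65.0% of those numbered 4000 and over. In the lightest fish the averages were 85.1% and 59.8%. A numbering that follows which fish had reads and a shared origin of these clusters both give such values, so they cannot be told apart here.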
